A study of Mus musculus with 6 samples.

How the data were processed

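RNA was measured in 6 mouse libraries, 1 per group, from C57BL/6 mice. Glioma-initiating cells (GICs), tumor cells that can seed a new glioma, of the line 7080 had been injected into the brains of young and old mice. The tumors were collected once the mice showed symptoms, and GIC cultures were re-established from them. The tumor groups were young, old, and old with NMN given before the tumor, and the 3 GIC groups carry the same names. NMN is written as in the labels, where it is not spelled out; its usual expansion is nicotinamide mononucleotide, a precursor of NAD+. Its dose, route and duration, the ages, and the number of mice behind a library are not given in the sources used here.

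Per the labels' protocols, total RNA was extracted with a TRIzol column system, ribosomal RNA was depleted, stranded libraries were made and read pairs were sequenced on an Illumina instrument. Per the submitters' processing notes, the tools were bcl2fastq 1.8.4, Trim Galore 0.6.2, STAR 2.5.4b, Cufflinks 2.2.1 and Cuffdiff, with the GRCm38 build. The authors deposited FPKM values, which are fragment counts scaled by transcript length and by library size, in 1 table for the 3 tumors and 1 table for the 3 GIC cultures. The gene annotation, the Cuffdiff normalization mode and whether strand was used in counting are not given in the sources used here. Strandless counting would mix a gene with its antisense or overlapping partner, and fragments of near-identical copies, such as processed pseudogenes, can be assigned to the wrong row. The 2 tables were treated as normalized separately, so differences within a table were set side by side. Levels were compared between tumors and GICs only for microglia markers, Ptprc and B2m, in the closing section.

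The values cover 46951 rows for tumors and 46952 rows for GICs, after 2 empty lines in each. A row can name several genes of overlapping loci (1064 rows in the tumor table, 1065 in the GIC table), and such a row is named here with all its genes where it matters. Loci in the tables start counting from 0 and are printed from 1. GENCODE M21, which is on GRCm38, supplied gene identifiers, gene types, gene coordinates and transcript sequences; 99.9% of the 43881 rows matched to it by symbol overlapped the GENCODE gene.

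From the deposited FPKM values, log2 differences of FPKM plus a pseudocount of 1 were computed, among rows whose highest value over the 3 libraries of a table was at least 1 FPKM. This left 14335 rows in tumors, of which 12674 named a protein-coding gene, and 12809 in GICs, of which 11207 did. These differences understate changes of low genes. With 1 library per group there are no replicates, so no test, SD or p-value between conditions exists; a difference of 2-fold or more (a log2 difference of 1 or more in size) is a rule of size and compares 2 libraries. For each of 44 gene lists, the median difference over its members was ranked among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. The resulting percentile describes these libraries, and lists with under 5 measured members got none. Lists used rows that name 1 gene; rows shared by several genes were added in an alternative.

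The genes named were fixed by a rule: the 12 highest and 12 lowest differences in each of 4 comparisons among rows with at least 5 FPKM in 1 of the 2 libraries, without symbols of the most common predicted genes, small RNA classes and receptor segments; up to 4 members per list; and 12 fixed genes. The symbol rule let through some small RNA genes and pseudogenes, such as mt-Tq, AF357399, Scarna8, Vaultrc5, Rpph1 and Itpa-ps1. The comparisons, lists, gene rule and the alternatives on pseudocount (0.1 and 0.5), filter (none and 5 FPKM), scaling (median of ratios, and rescaling to TPM) and row classes were fixed before the data were examined. Added after the data were seen were protein-coding rows only, shared rows in the lists, a correction for a trend with transcript GC content, and every value by chromosome.

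Old minus young and NMN-before minus old share the old library, which alone makes them correlate negatively. A reference value was therefore taken from 1000 random permutations of each row's 3 values, which spread the counts evenly over the 3 libraries. Tumor and GIC differences share no library; for these the overlap that independent lists of the same sizes would give was computed.

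The FPKM values were also used to recover the depth of each library. Low FPKM values of genes with a single transcript of 1500 to 12000 bases were whole multiples of 1 fragment within 0.05 for 96.6% to 98.3% of values. The depth was 15.1 M fragments (M for mega) for the young tumor, 11.3 for the old tumor and 18.8 for the NMN-before tumor, and 12.7, 9.68 and 9.74 M for young, old and NMN-before GICs. For a transcript with 1 kb of effective length, 5 FPKM then has a 95% Poisson interval from 4.04 to 6.12 in the deepest library and from 3.69 to 6.62 in the shallowest. A floor of 3 fragments corresponds to 0.159 FPKM in the deepest and 0.310 in the shallowest. These intervals cover counting error only, since PCR copies are not independent molecules, and say nothing of differences between mice or cultures.

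On simulated data with the real genes (13800 rows past the filter for tumors and 12233 for GICs), 100.0% of genes changed 4-fold were recovered in both directions for both tables, and 7.5% (tumors) and 3.5% (GICs) of lists with no change fell outside the 2.5th to 97.5th percentile. The changed genes had a mean of at least 5 FPKM, and the noise was independent between genes, without fragment counting. Recovery of a 4-fold change by the 2-fold rule was therefore nearly certain in advance, and only checks the computation. The unchanged lists held random genes, so their share does not cover lists of genes that vary together. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.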

Results

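Gene expression was measured by RNA-seq in tumors of the mouse glioma-initiating cell line 7080 grown in the brains of young mice, old mice and old mice given NMN before the tumor, and in glioma-initiating cells (GICs) cultured from such tumors. The series title asks for gene signatures of age in these tumors. Each of the 6 groups is 1 library, so every difference below compares 2 libraries and has no replicate check. The libraries listed 13366, 13648 and 13640 rows at 1 FPKM or more in young, old and NMN-before tumors, and 12077, 11944 and 11903 in the matching GICs. The depth was estimated at 11.3 to 18.8 M fragments for tumors and 9.68 to 12.7 M for GICs, where M is mega. Values are FPKM as deposited, differences are log2 of FPKM plus 1, and a list percentile gives the place of its median among 10000 random lists of matched expression.

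The old tumor had higher neuron and microglia markers and higher Igkc and Ighm than the young tumor, and lower values of interferon-stimulated, activity-induced, hypoxia and mitosis genes. Whether the old tumor piece held a larger share of host tissue was not tested for this comparison. The Xist row, given in the closing section, was at 16.5 FPKM in the old and 8.54 in the young tumor. Gad2, a GABA-synthesizing enzyme (chromosome 2, 22622205 to 22693874, plus strand), was at 8.82 FPKM in the old and 1.96 in the young tumor. Its neighbors among the highest differences were Slc32a1, the vesicular GABA transporter, Tac1, the substance P precursor, and Zcchc12, with log2 differences of 1.54, 1.64 and 1.94. Of the 16 neuron markers, 14 were higher in the old tumor and 2 lower, with a median log2 difference of 0.30, above all 10000 random lists. Astrocyte markers were higher in 7 of 11 (0.21, percentile 99.96) and erythroid markers in 5 of 5 (0.41, percentile 99.3). Gad1 was at 20.2 against 9.39 FPKM and Slc12a5 at 10.7 against 6.12. The hypothalamic peptide gene Oxt was listed at 9.56 FPKM in the old tumor and at 0 in the other 2 tumors. Ttr, transthyretin of the choroid plexus (chromosome 18, 20665280 to 20674321, plus strand), was at 151 FPKM in the old tumor, 24.0 in the young and 9.01 in the NMN-before tumor.

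Microglia markers and complement genes were higher in the old tumor. All 12 microglia markers were higher, with a median of 0.72, above all random lists; P2ry12 was at 5.86 against 1.82 FPKM and Cx3cr1 at 11.6 against 6.17. Complement genes were higher in 6 of 7 measured members (median 0.47, percentile 99.99), C1qa at 132 against 88.8 FPKM. Monocyte and macrophage markers had a median of 0.16 (percentile 86.0), inside the range of random lists, with the lysozyme gene Lyz2 at 290.4 against 128 FPKM. The immunoglobulin genes Igkc (77.02 against 5.55 FPKM) and Ighm (34.6 against 4.10) were the members of the B cell list furthest apart, of which 3 were measured. T and NK cell markers were low, with Cd3g at 1.94 against 0.759 FPKM and Cd4 at 0.866 against 1.12. Oligodendrocyte markers had a median of 0.35 (percentile 99.99), but went both ways: Mobp was at 54.1 against 24.6 FPKM while Cnp was at 193 against 346.

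Lower in the old tumor were 14 of 15 interferon-stimulated genes (median -0.58), 16 of 17 activity-regulated immediate early genes (-0.57), 12 of 13 hypoxia genes (-0.49), 11 of 14 glycolysis genes (-0.37) and all 15 mitosis genes (-0.34), each median below all random lists. Isg15 was at 44.5 FPKM in the old and 76.5 in the young tumor, Npas4, a transcription factor induced by neuronal activity, at 0.226 against 4.0003, Fosb at 1.64 against 6.33, and the lactate dehydrogenase gene Ldha at 361 against 637. Fibroblast markers were lower in 7 of 8 members (-0.57), with Col1a1 at 0.737 against 3.87 FPKM. Mesenchymal glioma genes were lower in 12 of 14 (-0.44), with S100a6 at 298 against 689 FPKM and the collagen crosslinker Lox at 0.347 against 2.66. With rows shared by several genes, the medians of interferon-stimulated and mesenchymal glioma genes were -0.39 and -0.26, still at percentiles 0.00 and 0.27. Oligodendrocyte precursor markers were lower in 8 of 11 (-0.28, percentile 0.58); with rows shared by several genes the median was -0.18 at percentile 10.2.

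Among coding genes with at least 5 FPKM in 1 of the 2 libraries, the lowest in the old tumor were Rrp7a, a ribosome biogenesis gene (chromosome 15, 83113433 to 83122801, minus strand; 58.1 against 271 FPKM), the cell cycle inhibitor Cdkn1c (8.53 against 39.0), Fam49b (chromosome 15, 63929097 to 64060478, minus strand; 46.2 against 152) and the retinoic acid synthesis gene Aldh1a3 (3.03 against 12.04). Asap1, which lies next to Fam49b, was at 17.5 against 49.1 FPKM. Among the fixed genes, Sirt1 (5.47 against 4.69 FPKM), Nampt, which makes NMN in cells (25.7 against 26.5), Sox2 (79.4 against 76.96), Cdkn1a (24.2 against 24.8) and Bdnf (1.32 against 1.23) differed little. NAD+ genes (14 measured, median 0.05, percentile 65.1) and sirtuins (6 measured, 0.00, percentile 56.7) lay inside the range of random lists, although Sirt2 was at 166 against 285 FPKM. In all, 229 rows were higher and 144 lower by 2-fold, of which 84 and 54 named protein-coding genes; 152 of the 373 rows were listed at 0 in 1 of the 2 libraries. At a pseudocount of 0.1 the counts were 542 and 302, and counts of the other comparisons were larger in the same way. Of 36 lists, 12 medians lay in the lowest 2.5% of random lists and 7 in the highest 2.5%, where lists of random genes would give 1.8 in all. The counts were 11 and 13 of 36 for NMN-before against old tumors. In GICs they were 7 and 5 of 29 for old against young, and 8 and 3 of 29 for NMN-before against old. A median outside the range of random lists was therefore common in every comparison.

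In the NMN-before tumor, neuron, fibroblast, hypoxia and heat shock genes were higher than in the old tumor, and hemoglobin, astrocyte and Ttr values were lower. Neuron markers were higher in 15 of 16 members, with a median of 0.85, above all random lists. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, was at 90.8 against 23.9 FPKM, Snap25 at 221 against 92.1 and Nefm at 11.03 against 4.34. Nptx2, a pentraxin at excitatory synapses (chromosome 5, 144545902 to 144557478, plus strand), was at 30.7 against 3.66, and the neuropeptide genes Cck and Vgf were at 47.3 against 8.90 and 35.6 against 7.27. Arc, an activity-induced synaptic gene, was at 15.1 FPKM against 4.19 in the old and 8.84 in the young tumor. Bdnf, a neurotrophin, was at 4.64 against 1.32 and 1.23. Activity-regulated genes as a list were higher in 13 of 17 members (median 0.41, above all random lists), while Fos was at 36.7 against 35.3 FPKM. Against the young tumor the same list was lower in 12 of 17 members (-0.30, below all random lists). Astrocyte markers were lower in 10 of 11 members (median -0.39, below all random lists), with the water channel gene Aqp4 at 24.98 against 59.8 FPKM. Oligodendrocyte markers were lower in 11 of 12 (-0.29, percentile 0.04), and microglia markers were divided evenly (-0.02, percentile 40.4). Mural cell markers were higher in 6 of 9 (0.28, percentile 98.1) and endothelial markers in 7 of 11 (0.19, percentile 94.6).

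Fibroblast markers were higher in all 8 measured members in the NMN-before tumor, with a median of 1.04; Dcn was at 6.20 against 2.12 FPKM and Mgp at 47.4 against 22.1. Hypoxia genes were higher in 12 of 13 members (0.72), among them Adm at 5.07 against 1.35 and Ankrd37 at 9.23 against 3.26, and glycolysis genes in 13 of 14 (0.46). The small heat shock gene Hspb1 (chromosome 5, 135887919 to 135889563, plus strand) was at 25.4 FPKM against 2.69 in the old and 2.55 in the young tumor, and all 8 heat shock genes were higher (median 0.62, percentile 99.99). Mesenchymal glioma genes (12 of 14 higher, 0.47), mitosis genes (15 of 15, 0.36) and DNA replication genes (11 of 12, 0.39) were higher as well, each above all random lists. The metalloelastase gene Mmp12 was at 8.37 against 1.3998 FPKM.

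All 5 erythroid markers were lower in the NMN-before tumor (median -1.72), Hbb-bs at 33.2 against 147 FPKM. Proneural glioma genes were lower in 9 of 10 members (-0.37, percentile 0.01), led by Sox10, a transcription factor of the oligodendrocyte lineage, at 7.30 against 24.5 FPKM. The growth factor gene Mdk was at 6.84 against 31.3 and the homeobox gene Hopx at 27.5 against 104. Interferon-stimulated genes were lower in 11 of 15 (-0.33, percentile 0.01). NAD+ genes (median -0.06, percentile 21.6) and sirtuins (-0.11, percentile 13.5) lay inside the range of random lists, and Nampt was at 31.2 against 25.7 FPKM. The row shared by Spp1 and Gm42793 was at 61.4 FPKM, against 41.5 in the old and 21.2 in the young tumor. In all, 267 rows were higher and 179 lower by 2-fold, of which 187 and 83 named protein-coding genes.

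**Figure D1:**
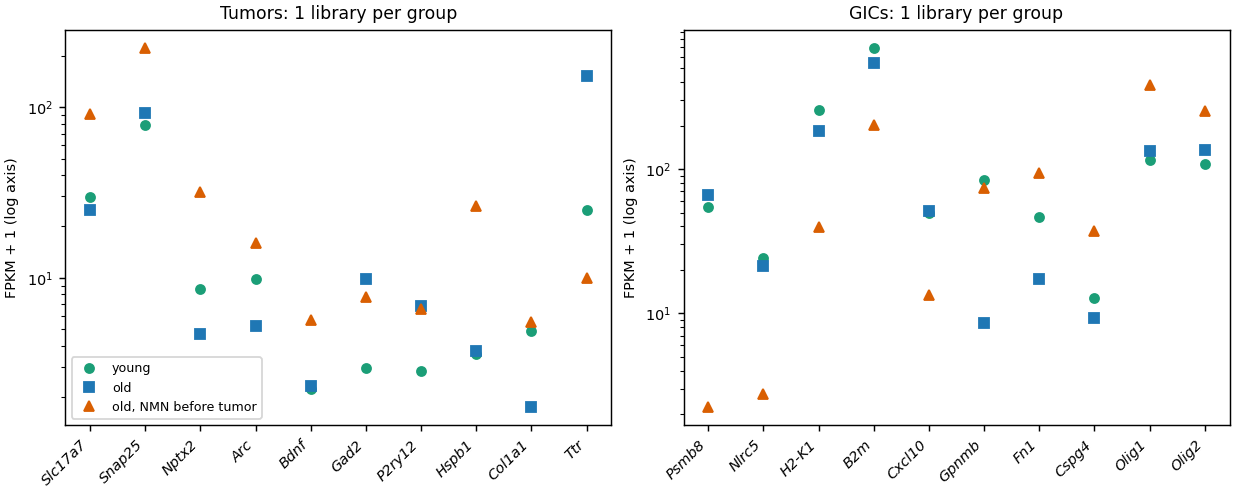
FPKM plus 1 on a log axis of 10 genes in the 3 tumors (left) and 10 in the 3 GIC cultures (right), 1 point per library. Slc17a7 stands at 90.8 FPKM in the NMN-before tumor against 23.9 in the old tumor, and Psmb8 at 1.23 FPKM in the NMN-before GICs against 65.3 in the old GICs.

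In culture, GICs of the old-host tumor had less of several matrix and mesenchymal genes than GICs of the young-host tumor, and more of mitosis, glycolysis and cholesterol synthesis genes. Gpnmb, a transmembrane glycoprotein (chromosome 6, 49036546 to 49070929, plus strand), was at 7.51 FPKM in old GICs against 83.0 in young GICs and 73.1 in NMN-before GICs. Tenascin C, Tnc (chromosome 4, 63959785 to 64047015, minus strand), was at 4.58 against 28.8 FPKM, fibronectin, Fn1, at 16.3 against 45.8, and Igfbp5 at 6.48 against 50.5. Mesenchymal glioma genes were lower in 11 of 12 measured members (median -0.54, below all random lists) and matrix genes in 9 of 11 (-0.28, percentile 0.20). The astrocyte filament gene Gfap was at 3.21 against 11.4 FPKM and the cell cycle inhibitor Cdkn2b at 1.65 against 9.34. The row shared by Spp1 and Gm42793 was at 97.3 against 237 FPKM. Senescence-associated genes were lower in 7 of 9 (-0.58, percentile 0.04), yet the chemokine gene Ccl2 on this list was at 6.02 against 0.236 FPKM.

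Higher in old GICs were all 15 mitosis genes (median 0.39, above all random lists), with Cdk1 at 226 against 146 FPKM and Ccnb2 at 15.5 against 7.67. Of 14 glycolysis genes 13 were higher (0.32, percentile 99.96), Pfkl at 42.2 against 21.2, and all 10 cholesterol synthesis genes (0.39, above all random lists), Hmgcs1 at 64.6 against 40.9. Sirtuins had a median of 0.03 (percentile 63.5), with Sirt6 at 7.14 against 2.93 and Sirt5 at 3.04 against 6.44. NAD+ genes had a median of 0.19 at percentile 97.2 (97.9 with rows shared by several genes, in the highest 2.5%), with Nampt at 47.4 against 33.1 and Nmnat2 at 4.49 against 2.16. MHC class I genes were lower in 6 of 10 members (-0.26, percentile 0.41), with H2-K1 at 182 against 258 FPKM. In all, 157 rows were higher and 202 lower by 2-fold, of which 61 and 98 named protein-coding genes. Cyct, Uba1y and RP24-366L10.4 were among the highest differences; Cyct and Uba1y have related genes elsewhere in the genome, and the assignment of fragments between them was not tested.

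GICs of the NMN-before tumor had far less RNA of the MHC class I pathway and of interferon-stimulated genes than old GICs, and more of oligodendrocyte precursor and astrocyte genes. The immunoproteasome gene Psmb8 (chromosome 17, 34197721 to 34201454, plus strand) was at 1.23 FPKM against 65.3 in old and 54.0 in young GICs; its locus in the tables is shared with Tap2, a row of its own. Nlrc5, the transactivator of MHC class I genes (chromosome 8, 94434356 to 94527272, plus strand), was at 1.77 against 20.2 and 23.2 FPKM. H2-K1 was at 38.7 against 182 and B2m, the MHC class I light chain, at 202 against 547. All 10 MHC class I genes were lower, 7 of them by 2-fold, with a median of -1.73. Of 10 interferon-stimulated genes 9 were lower (median -1.28), Cxcl10 at 12.4 against 50.4 FPKM and Usp18 at 0.751 against 5.44, and Irf7 was at 0.718 against 0.605. All 6 measured inflammatory genes were lower (-1.38), Ccl5 at 1.27 against 11.2 and Icam1 at 0.853 against 6.72. Each of these 3 medians lay below all random lists. Among the lowest differences were also the guanylate-binding protein gene Gbp3 at 2.61 against 19.8 FPKM, the row shared by Igtp and Irgm2 at 1.56 against 19.2, and Tgtp2 at 0.0767 against 5.04. Lyz2 was at 4.33 against 2.21 FPKM and Cd68 at 4.61 against 5.51. B2m and Irf7 fall outside the naming rule and were chosen after their values were seen.

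Oligodendrocyte precursor markers were higher in 8 of 9 members in NMN-before GICs, 5 of them by 2-fold, with a median of 1.16, above all random lists. The proteoglycan gene Cspg4 was at 36.3 against 8.27 FPKM, Olig1 at 379.9 against 132 and Olig2 at 254 against 136. Proneural glioma genes were higher in 6 of 7 (0.68, percentile 99.98) and astrocyte markers in 7 of 9 (0.74, percentile 99.98), with Aldoc at 170.4 against 40.8 FPKM. Kcnj10, an inward rectifier potassium channel gene, was at 43.4 against 6.11, Olfm2 (chromosome 9, 20667690 to 20746349, minus strand) at 40.2 against 3.57, and Fn1 at 93.5 against 16.3. The NAD+ list was lower in 10 of 13 members (median -0.35, percentile 0.64; -0.25 at percentile 2.81 with rows shared by several genes), with Nampt at 27.4 against 47.4 and Nmnat2 at 2.44 against 4.49. Sirt1 was at 7.08 against 11.9 FPKM and Sirt6 at 9.84 against 7.14. The cyclin genes Ccne1 (13.9 against 32.8 FPKM) and Ccne2 (9.19 against 19.96) led the DNA replication list, lower in 10 of 12 (-0.25, percentile 2.25; -0.20 at percentile 6.37 with shared rows), while Mki67 was at 58.6 against 65.3. In all, 418 rows were higher and 295 lower by 2-fold, of which 292 and 181 named protein-coding genes.

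**Figure D2:**
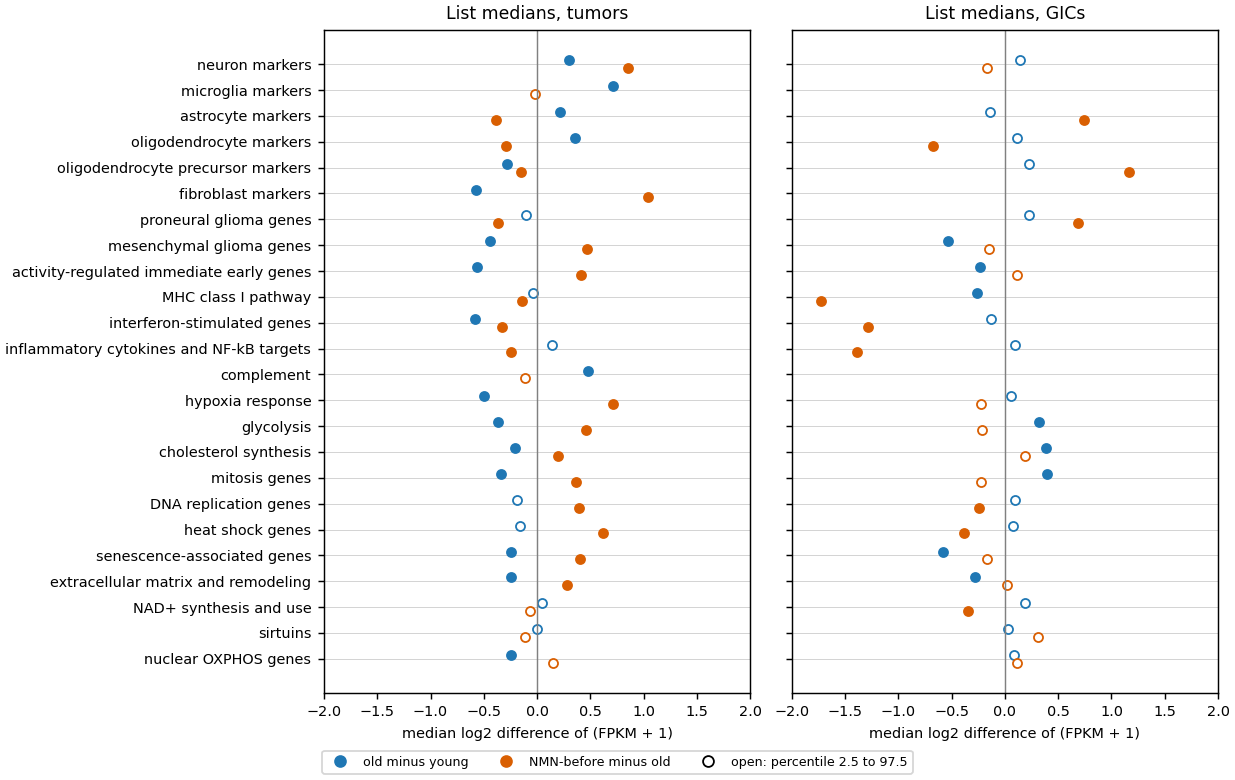
Median log2 difference of FPKM plus 1 over the members of 24 gene lists in tumors (left) and GICs (right), old minus young in blue and NMN-before minus old in orange; filled points lie in the lowest or highest 2.5% of random lists, and lists with under 5 measured members have no point. Neuron markers stand at 0.85 for NMN-before minus old tumors, and MHC class I genes at -1.73 for NMN-before minus old GICs.

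Against young libraries, the NMN-before tumor had higher neuron markers in 16 of 16 members, 12 by 2-fold (median 1.15), and higher microglia markers in 12 of 12 (0.71), both above all random lists. Its interferon-stimulated genes were lower in 14 of 15 (-0.90) and its oligodendrocyte markers in 8 of 12 (-0.40), both below all random lists. In NMN-before GICs, MHC class I genes were lower than in young GICs in 9 of 10 members (-1.97), interferon-stimulated genes in 10 of 10 (-1.24) and mesenchymal glioma genes in 10 of 12 (-0.54), and oligodendrocyte precursor markers were higher in 8 of 9 (1.56). Counts of rows 2-fold higher and lower were 400 and 140 for tumors and 459 and 389 for GICs. After rescaling to TPM, the GIC counts were 618 and 837, so that 42.5% rather than 54.1% of these rows were higher.

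Whether NMN-before libraries lay opposite to the old ones was asked row by row. The old library stood 2-fold apart from both others on the same side in 118 rows in tumors and 126 rows in GICs. Permuting each row's 3 values gave a mean of 149.9 rows (119 to 184) for tumors and 210.2 (174 to 249) for GICs. That mean is by construction the average of the counts for the 3 libraries, so a count below it does not show whether NMN-before lay opposite to old. The NMN-before library stood apart in 194 and 349 rows, and the young library in 138 and 157. In GICs, the NMN-before differences rose with transcript GC content. The Spearman rho was 0.245 against old and 0.206 against young GICs, but -0.049 for old minus young. The counts of rows apart and of 2-fold rows were not corrected for this trend. Among protein-coding rows the counts for the old, young and NMN-before libraries were 36, 48 and 130 in tumors and 41, 72 and 258 in GICs. Examples with the old library apart were Ttr in tumors and Gpnmb, Tnc and Ccl2 in GICs. The correlation across rows of the 2 differences was -0.46 in tumors and -0.36 in GICs, against -0.50 from permuted values, with a covariance of -0.10 against -0.11 in tumors and -0.10 against -0.15 in GICs.

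Across 12222 rows tested in both tables, which are not independent replicates, old minus young had a Pearson r of 0.04 and a Spearman rho of -0.03, and NMN-before minus old had -0.12 and -0.09. Of these rows, 10 were 2-fold higher and 16 lower in both kinds for old minus young (0.843 and 0.960 for independent lists), and 8 and 11 went opposite ways (1.14 and 0.709). For NMN-before minus old, 16 were higher and 8 lower in both (3.53 and 1.53), and 25 and 21 went opposite ways (2.29 and 2.36). Many of these rows were predicted or small RNA genes, such as Snord7, Rny1 and Rpph1. Among 10197 rows with protein-coding genes and no predicted or small RNA gene, 1 gene (Pid1) was 2-fold higher with age in both kinds, where independent lists would share 0.078, and 2 genes were lower in both (Igf2bp3 and S100a6), where they would share 0.186; none went opposite ways. For NMN-before minus old, 7 rows were higher in both and 3 lower in both (Enpp2, Lxn and the row shared by Igtp and Irgm2), where independent lists would share 1.75 and 0.429. In opposite directions, 7 rows were higher in tumors and lower in GICs, among them Syn1, and 6 the reverse, among them Id4, where independent lists would share 0.992 and 0.756. These names were chosen after their values were seen.

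Medians by chromosome were computed after the data were seen, over rows with a mean of at least 5 FPKM. They passed 0.2 in size in GIC comparisons and in no tumor comparison. Genes of chromosome 10 (416 rows) had a median log2 difference of 0.24 in old minus young GICs and 0.25 in NMN-before minus old GICs. Genes of chromosome X (263 rows) stood at 0.27 and -0.39, and those of chromosome 12 (303 rows) at 0.21 and -0.20. Chromosome 14 (261 rows) stood at -0.21 in NMN-before minus old GICs. After a correction for transcript GC content, chromosomes 12 and 14 stood at -0.15 and -0.14 in NMN-before minus old GICs, below the size of 0.2 by which chromosomes were named. In NMN-before minus young GICs, chromosome 10 stood at 0.50 and chromosome 6 (417 rows) at 0.30. In tumors, medians ranged from -0.14 to 0.17 for old minus young and from -0.10 to 0.12 for NMN-before minus old. Some tumor medians also lay far outside random gene sets. In old minus young tumors, chromosome X stood at 0.174 (SD of random medians 0.016), chromosome 9 at -0.142 (0.012) and chromosome 15 at -0.139 (0.014).

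**Figure D3:**
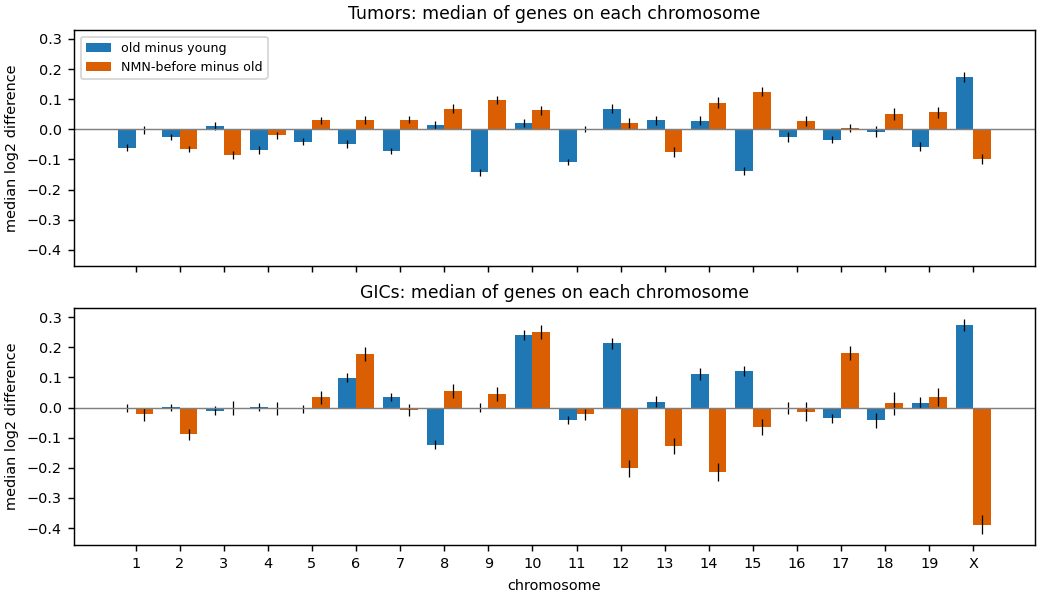
Median log2 difference of FPKM plus 1 over the genes of each chromosome in tumors (top) and GICs (bottom), old minus young in blue and NMN-before minus old in orange; error bars are 1 SD of medians of random gene sets matched on expression and size. Chromosome 10 stands at 0.24 and 0.25 and chromosome X at 0.27 and -0.39 in GICs.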

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

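Old minus young went opposite ways in tumors and in GICs for 3 gene lists, given as list medians with tumors first. Mitosis genes stood at -0.341 and 0.393, glycolysis genes at -0.366 and 0.319, and cholesterol synthesis genes at -0.211 and 0.389. In NMN-before minus old, astrocyte markers stood at -0.385 in tumors and 0.741 in GICs, oligodendrocyte precursor markers at -0.149 and 1.162, proneural glioma genes at -0.365 and 0.682, DNA replication genes at 0.390 and -0.245, and heat shock genes at 0.615 and -0.382. In NMN-before minus young, astrocyte markers stood at -0.242 and 0.944, oligodendrocyte precursor markers at -0.306 and 1.556, proneural glioma genes at -0.363 and 1.046, hypoxia genes at 0.217 and -0.294, heat shock genes at 0.497 and -0.434, and integrated stress response genes at 0.158 and -0.359. Each was picked out because the median tumor difference and the median GIC difference lay on opposite sides of 0, with both medians outside the range of random lists. With rows shared by several genes, 4 of these medians moved inside the range of random lists: oligodendrocyte precursor markers in NMN-before minus old tumors (-0.088, percentile 3.77), DNA replication genes in NMN-before minus old GICs (-0.197, percentile 6.37), and astrocyte markers in NMN-before minus young for tumors (-0.171, percentile 3.91) and GICs (0.074, percentile 72.1). The last of these was -0.363 with the 5 FPKM filter. With 1 library per group, the difference between tumors and GICs was not tested.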

How the results depend on the processing

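Counts of genes 2-fold apart depend strongly on low values, and are given here as higher and lower. At a pseudocount of 0.1 they were 542 and 302 for old against young tumors, 545 and 407 for NMN-before against old tumors, 859 and 306 for NMN-before against young tumors, 346 and 527 for old against young GICs, 751 and 664 for NMN-before against old GICs, and 761 and 783 for NMN-before against young GICs, with the old library apart from both others 331 times in tumors and 370 times in GICs (against 118 and 126 at a pseudocount of 1). At 0.5, the counts that moved by over 1.5 times were 274 lower (NMN-before against old tumors), 611 higher (NMN-before against young tumors), 329 lower (old against young GICs), 452 lower (NMN-before against old GICs), 587 lower (NMN-before against young GICs), and 195 and 212 for the old library apart. With a filter of 5 FPKM, in the same order of comparisons, they were 91 and 67, 165 and 86, 265 and 83, 78 and 90, 275 and 173, and 202 lower, with 53 and 69 for the old library apart. Rescaled to TPM, which raises all values against the pseudocount, they were 486 and 234, 423 and 368, 687 and 241, 306 and 504, 662 and 595, and 837 lower, with 245 and 285. Without predicted and small RNA genes they were 97 and 56, 85 lower, 66 lower, 69 and 99, and 176 lower (NMN-before against old GICs), with 37 and 47. With protein-coding genes only, chosen after the data were seen, they were 84 and 54, 83 lower, 62 lower, 61 and 98, and 181 lower, with 36 and 41. By construction, a smaller pseudocount widens every difference, and the filters hold fewer genes. Scaling by median of ratios moved no count by over 1.5 times (437 and 287 for NMN-before against old GICs), and no filter cannot, since below 1 FPKM a 2-fold difference is out of reach at a pseudocount of 1. Of 144 counts and correlations 65 moved, all of them counts. Of 2064 list medians 1849 stayed within 1 SD of random list medians (0.1 for lists under 5 members), 212 moved further and 3 reversed: astrocyte markers in NMN-before minus young GICs were at -0.3630 with the 5 FPKM filter (0.94 otherwise), and ribosomal protein genes in old minus young GICs at 0.0067 after the GC correction and 0.0041 with shared rows (-0.03 otherwise), both chosen after the data were seen; the cause was not tested. Of 1116 values of named genes 21 moved by over 0.1 and over 0.5 of their size, and 0 reversed. Depth limits low genes most in old and NMN-before GICs, where 3 fragments per effective kb correspond to 0.310 and 0.308 FPKM.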

Other observations

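A stretch of chromosome 15 stood out in the young tumor, and its genes were chosen after their values were seen. The median over the whole chromosome was -0.139 in old minus young tumors and -0.023 in NMN-before minus young tumors. The oncogene Myc (61985341 to 61990374, GRCm38) was at 383 FPKM in the young, 217 in the old and 227 in the NMN-before tumor. The row of Pvt1, the noncoding neighbor of Myc, which is shared with Gm27718, Gm27913 and Gm27957, was at 1234, 807 and 661. Fam49b was at 152, 46.2 and 53.2 FPKM, while Efr3a further along was at 25.3, 22.3 and 31.8. In GICs, Myc was at 381 FPKM in young, 381 in old and 246 in NMN-before cultures, and Fam49b at 38.1, 48.5 and 39.4. Rrp7a and Serhl, which share a locus in the tables, were at 271 and 51.9 FPKM in the young tumor against 58.1 and 20.9 in the old, while their neighbor Poldip3 was at 53.04 and 42.2.

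Xist, Ddx3y and Eif2s3y belong to a list of sex-linked genes that was fixed beforehand as a sample check, while Uba1y does not. The row of Xist, the RNA of the inactive X chromosome (shared with Gm27733 and Gm27927), was at 8.54, 16.5 and 21.3 FPKM in young, old and NMN-before tumors, and at 0.0890, 0.512 and 0.204 in the matching GICs. The Y chromosome genes were present in all 6 libraries, with Ddx3y at 23.1, 21.2 and 24.7 FPKM in tumors and 20.7, 27.3 and 28.2 in GICs.

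For the lower MHC class I and interferon genes of NMN-before GICs, all tests were chosen after the pattern was seen. Microglia with the marker levels of the old tumor are excluded as the source in the old culture, because microglia markers there reached a median of 1.7244% of their old tumor values, where B2m would need 29.8%. Sall1 and Olfml3, at 59.6% and 59.3%, lay above that share and the other 10 markers at 9.73% or less. The leukocyte gene Ptprc was at 0.046 FPKM in old GICs, 1.15% of its old tumor value. Immune cells of other kinds, or without microglia markers, were checked by Ptprc only. Loss of the H2 region of chromosome 17 alone is excluded, because the members on other chromosomes had a median of -1.4855, and a trend with GC content because the median stayed at -1.5633 once it was removed. An effect of NMN and a difference between any 2 cultures stay open, since 1 culture per group cannot separate them.

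For the higher neuron markers of the NMN-before tumor, both tests were chosen after the pattern was seen. A larger share of host brain of every kind predicts higher oligodendrocyte and astrocyte markers. This was not met, with medians of -0.2886 and -0.39. These lists do not settle the host share. Cultured GICs also expressed astrocyte members such as Aldoc, so tumor cells can contribute to that list. Gfap, however, was at only 3.21 FPKM in old and 6.41 in NMN-before GICs. Of the 12 oligodendrocyte markers, 5 were measured in GICs, so a part from tumor cells is less clear for that list. A trend with GC content is excluded, because the neuron median was 0.8414 once it was removed. A larger share of host brain stays open. The Xist row, at 0.512 FPKM or less in GICs, was at 21.3 FPKM in the NMN-before and 16.5 in the old tumor. That goes with a larger host share, but it rests on 1 row, and the sex of the hosts is not stated here. A piece with more neuron-rich tissue and an effect of NMN also stay open and were not tested.

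For the chromosome-wide differences between GIC libraries, all tests were chosen after the pattern was seen, and the smallest median was 0.1382 (chromosome 14) after removing a GC trend and 0.1944 after removing a length trend, which excludes both as the whole source for chromosomes 10, 12, 14 and X in old minus young and NMN-before minus old GICs, although the GC correction took chromosomes 12 (-0.20 to -0.15) and 14 (-0.21 to -0.14, with an SD of random sets of 0.03) under the size of 0.2 in NMN-before minus old. Chromosome 6, which stood apart in NMN-before minus young GICs, was at 0.31 after the GC and 0.30 after the length correction there, with a smallest segment of 0.26. Copies of whole chromosomes predict a shift in each of 4 position segments of a chromosome, and this was not met, with 0.0251 in a segment of chromosome 12. Without chromosome 12 the smallest segment stood at 0.1578, but this split decides nothing, since chromosome 12 was left out once its segments were known, and in NMN-before minus young GICs a segment of chromosome X stood at 0.0285 where its whole median was -0.11. Copies of the other chromosomes, age and NMN stay open.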
